A study of Homo sapiens with 8 samples.

How the data were processed

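RNA was taken from MDA-MB-231 cells transfected with 4 siRNAs (siC, siE1, siE2 and siE3), 2 libraries each. Per the labels, INTERFERin was the transfection reagent, RNA came from a Qiagen RNeasy kit and libraries followed Illumina procedures. The submitters' processing notes name TopHat 1.3.3, HTSeq, DESeq and the human genome build hg19. The strand setting, the gene annotation and any filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

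The deposited table has 3 header lines and, per the file headers, holds raw counts per gene symbol for the 8 libraries, with a fold and an adjusted p-value for each siRNA against the control. The authors' deposited count values were whole numbers and differed in total between libraries. The authors' deposited fold (a linear ratio) lay within 1% of the ratio of mean counts after scaling by size factors for 100% of the genes checked. The authors' deposited adjusted p-value columns were used only for the comparison with their calls.

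Groups came from the sample titles. Of 23368 symbols, 5492 had no count in any library. The filter filterByExpr of edgeR 4.0.16 kept 13395 genes, TMM scaling gave factors of 0.980 to 1.02, and the quasi-likelihood test (glmQLFit, glmQLFTest) was fitted once over the 8 libraries with a mean per group, which left 4 residual degrees of freedom. The common dispersion was 0.00166, a biological coefficient of variation of 4.08%. Contrasts were each siRNA against siC, the average of the 3 siRNAs against siC, and the siRNAs against each other, with Benjamini-Hochberg adjustment in each contrast and a threshold of 0.05. Fold changes are log2 values with SE, computed as the log2 fold change divided by the root of the F statistic, and levels are CPM scaled by TMM. R was 4.3.3.

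Before the data were examined, 40 gene lists with 1060 entries were fixed, along with the comparisons, the alternatives and the rule for naming genes. Lists with at least 5 tested members (37) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Markers of blood cells and fibroblasts had 3 and 4 tested members, and the 13 genes encoded by the mitochondrial genome had no row in the table, so these lists were not tested. Some gene and list results are not reported here. Named by rule were ESRRA, ESRRB, ESRRG, TNFAIP1, RHOA and MMP1, and then the 12 highest and 12 lowest averages among genes called the same way by all 3 siRNAs, with a mean of at least 5 CPM and all 6 siRNA libraries beyond both siC libraries (1054 higher and 957 lower genes qualified). The rule also took the 4 highest and 4 lowest genes for each siRNA that differed from siC and from both other siRNAs, and up to 4 members with the smallest p of each list described.

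On simulated counts with 200 changed genes, the test recovered 38%, 54% and 46% of genes seeded at a log2 change of 0.25 (siE1, siE2 and siE3, 13252, 13253 and 13262 genes), 92%, 98% and 98% at 0.5, and 100% at 1 and at 2. False calls were 5.17%, 5.38% and 8.51% of calls. The list test, with the TCA cycle lowered by 0.2 in simulated counts, called that list and 2 others.

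For the search of 3' UTR words, run after the differences between siRNAs had been seen, transcripts came from GENCODE v29 on GRCh38, which is not the authors' build, so that no coordinates are given. For 12373 tested genes (92.4%) the 3' UTR of the principal transcript, and the longest among several, was matched by symbol or synonym, and 1022 genes were not searched. Each of 15762 words of 7 bases present in at least 100 genes was tested for a shift in log2 fold change, with the most extreme t of 100 permutations of the fold changes over genes as reference. In 20 simulated runs with a word lowered by 0.15, that word ranked first in 18. Symbol matching was widened to synonyms after a first run had been seen, and in that first run the leading siE2 word was ATCTGCT.

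Alternatives were DESeq2 size factors, library size alone, no filter and a stricter filter on low counts (a mean of 1 CPM and 50 counts in total), the DESeq2 1.42.0 Wald test, limma-voom, fits of only the groups compared, the replicate number as a block, a fold limit of 1.5 and leaving out each library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the word search and plots. Replicates were compared by a chi-square of their counts over 12364 genes with a mean count of at least 20, and none agreed within sampling noise.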

Results

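RNA-seq libraries were made from MDA-MB-231, an established human triple-negative breast cancer line. The cells had been transfected, with the reagent INTERFERin, with a control siRNA (siC) or with 1 of 3 small interfering RNAs (siE1, siE2 and siE3) that direct the breakdown of the ESRRA mRNA. ESRRA encodes the orphan nuclear receptor ERRα (estrogen-related receptor α), known as a driver of mitochondrial energy genes. Each siRNA had 2 libraries, 8 in all, and every mean ± SD below has n = 2. The table held raw read counts for 23368 gene symbols. Total counts were 22047738 and 23624089 for siC, 22305207 and 25880548 for siE1, 22688294 and 22669757 for siE2, and 21835995 and 23586024 for siE3. Libraries of the same siRNA differed far less than libraries of different siRNAs, with a chi-square per degree of freedom of 3.11 to 5.12 within groups and 40.6 to 75.1 between groups. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

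ESRRA, the target, was lower with each siRNA. It stood at 63.9 ± 1.31 CPM (counts scaled to library size) under siC, 10.4 ± 0.113 under siE1, 8.06 ± 1.14 under siE2 and 8.43 ± 0.171 under siE3. The counts were 1379 and 1512 in the siC libraries, 228 and 271 with siE1, 205 and 168 with siE2, and 187 and 192 with siE3. The log2 fold change was -2.62 (SE 0.0857) for siE1, -2.99 (SE 0.0896) for siE2 and -2.92 (SE 0.0894) for siE3, so 16.3%, 12.6% and 13.2% of the control level remained (edgeR adjusted p = 7.2e-12, 6.0e-12 and 4.9e-12). ESRRA was higher under siE1 than under siE2 by 0.37 (SE 0.108, edgeR adjusted p = 0.0092) and than under siE3 by 0.30 (SE 0.108, edgeR adjusted p = 0.031). Between siE2 and siE3 the difference was -0.06 (SE 0.113, edgeR adjusted p = 0.67). The other family members, ESRRB and ESRRG, had 0 to 2 counts in every library and were not tested. Of 12 tested genes of the ERR family and its coregulators, ESRRA included, 2 rose and 5 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.36), with PPRC1 at -0.57 and NCOA2 at 0.59 in the average of the 3 siRNAs. Without ESRRA the median of that list turned from -0.05 to 0.03.

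**Figure D1:**
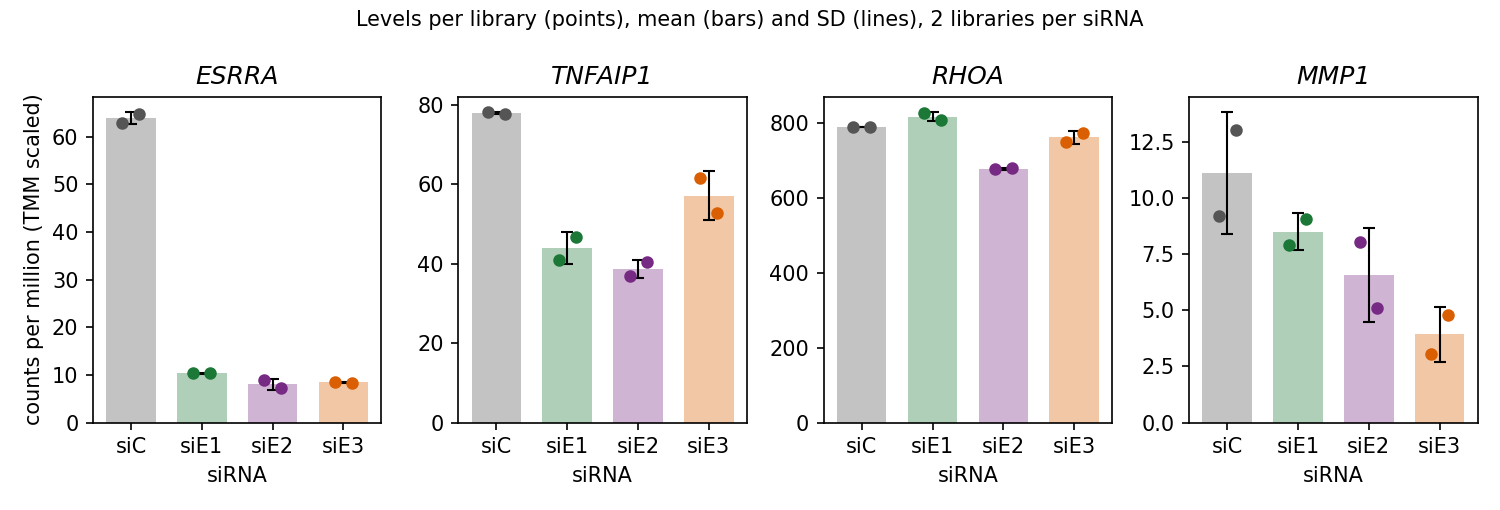
CPM of ESRRA, TNFAIP1, RHOA and MMP1 (vertical axes) in the libraries with the control siRNA siC and with siE1, siE2 and siE3 (horizontal axes). ESRRA fell from a mean of 63.9 under siC to 10.4, 8.06 and 8.43.

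TNFAIP1, RHOA and MMP1 were picked beforehand because published work on ERRα and cell movement had taken them up, so they are no independent evidence. TNFAIP1, an adaptor that brings the GTPase RHOA to the CUL3 ubiquitin ligase, fell from 78.0 ± 0.230 CPM under siC to 44.0 ± 4.09 (siE1), 38.7 ± 2.36 (siE2) and 57.2 ± 6.12 (siE3). Its log2 fold changes were -0.82, -1.01 and -0.45, and -0.76 in the average (SE 0.0613, edgeR adjusted p = 9.5e-08). CUL3 was at -0.22 in the average (SE 0.0388, edgeR adjusted p = 2.0e-04). RHOA mRNA was at -0.08 in the average (SE 0.0310, edgeR adjusted p = 0.055), and siE2 alone gave a call, at -0.22 (edgeR adjusted p = 1.5e-04). MMP1, the interstitial collagenase, went from 11.1 ± 2.72 CPM to 8.49 ± 0.823, 6.57 ± 2.09 and 3.93 ± 1.23, an average log2 fold change of -0.88 (SE 0.168, edgeR adjusted p = 4.4e-04), and siE1 on its own was not called (edgeR adjusted p = 0.12). By the authors' deposited adjusted p, MMP1 was below 0.05 with siE3 only (0.0024), and not with siE1 (0.41) or siE2 (0.13). Of the 6 genes around CUL3 and RHOA, 3 fell and 0 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.20). RHOA passed in the average with limma-voom (adjusted p = 0.036), without a filter on low counts (edgeR adjusted p = 0.045) and without siE3 replicate 2 (edgeR adjusted p = 0.020).

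Over 13395 tested genes, siE1 changed 6744 (3287 up, 3457 down), siE2 7560 (3736 up, 3824 down) and siE3 5643 (2858 up, 2785 down) at an edgeR adjusted p below 0.05. The average of the 3 siRNAs changed 6849 genes (3138 up, 3711 down). Most changes were small, and with at least 1.5-fold required the numbers were 1974, 2408 and 1335, and 1277 for the average. By the authors' deposited values, 5288, 6223 and 3792 genes had an adjusted p below 0.05, and 99.7%, 99.9% and 99.9% of them were called here, all with the same sign.

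All 3 siRNAs moved 2164 genes the same way, 1170 higher and 994 lower, and 338 of these (296 higher, 42 lower) by at least 1.5-fold each. Among those with at least 5 CPM and every siRNA library beyond both siC libraries, the highest average log2 fold changes were TMEM64 (2.21, SE 0.0659), the phospholipid scramblase PLSCR4 (2.14, SE 0.0978), TMEM65 (2.08, SE 0.0649), TMEM87B (2.05, SE 0.0688) and the p53-inducible TP53INP1 (1.93, SE 0.113). Next came NGEF (1.90), the calcium channel subunit CACNA2D1 (1.89), SLC22A18 (1.79), TRIB2 (1.70), ACLY (1.64), UHMK1 (1.64) and the mitochondrial thymidine kinase TK2 (1.62). ACLY, which makes cytosolic acetyl-CoA for lipid synthesis, went from 206 ± 10.5 CPM under siC to 622 ± 3.78, 610 ± 5.65 and 707 ± 19.6. After ESRRA the lowest averages were the kinesin KIF3B (-1.24, SE 0.0372), SCAMP5 (-1.22, SE 0.0612), FAM155B (-1.19), C5orf62 (-1.16), the sphingosine-1-phosphate exporter SPNS2 (-1.13), GPD1L (-1.10), MGC12916 (-1.09), SNHG4 (-1.07), LIN52 (-1.05), HS3ST3B1 (-1.01) and RPIA of the pentose phosphate pathway (-1.01). KIF3B was at -1.82 and -1.75 under siE1 and siE3 but at -0.15 under siE2, and GPD1L was at -2.50 under siE2 against -0.24 and -0.57. Independent lists of these sizes would share 196 higher and 205 lower genes, and 40 simulated sets of unchanged groups with common siC libraries and the spread between replicates shared at most 1. Correlations of log2 fold changes across genes, which are not independent replicates, were 0.467 (siE1, siE2), 0.502 (siE1, siE3) and 0.593 (siE2, siE3), against 0.507, 0.503 and 0.503 simulated, while covariances exceeded the simulated ones by 0.119, 0.0939 and 0.127. The siC libraries were not split, since each part would hold 1 library, and part of the excess may come from sharing them. A search made afterwards on the same fold changes found TACATTT or ACATTTA in the 3' UTR of 573 of 1143 shared higher genes (50.1%, 35.3% in lists matched on 3' UTR length and GC content) and 204 of 950 lower ones (21.5%, matched 29.9%). Among the genes named above they were in 10 of the 12 highest and 1 of the 10 lowest searched. Among shared higher genes with an average of at least 1 the share was 48.6% (86 of 177), close to that of all shared higher genes. Only the 12 highest stood above it, at 83.3%, so these cuts do not settle whether the share grows with the rise. Over all searched genes the share was 31.7%.

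**Figure D2:**
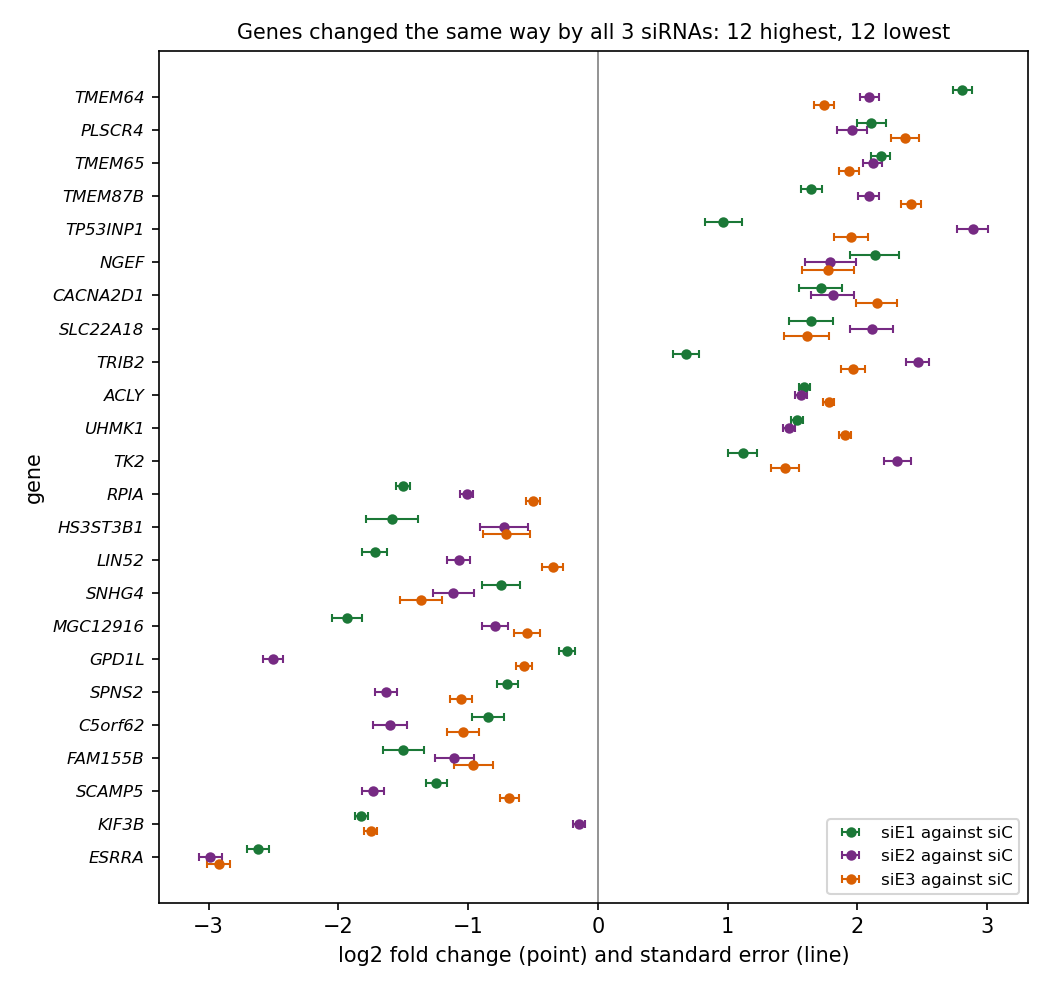
Log2 fold change against siC (horizontal axis) of the highest and lowest genes that siE1, siE2 and siE3 moved the same way (vertical axis), with standard errors. TMEM65 lay at 2.18, 2.12 and 1.93 under the 3 siRNAs, and KIF3B at -1.82, -0.15 and -1.75.

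Mitochondrial energy genes were lower in the average of the 3 siRNAs. Of 41 nuclear genes of respiratory complexes II to V, 36 fell and 0 rose in the average (median -0.24, camera adjusted p = 9.6e-10, adjusted p = 0.26 with an estimated correlation), and 18 fell with each siRNA. They included the ATP synthase subunit ATP5B (-0.58, SE 0.0314), SDHD (-0.52, SE 0.0425), CYC1 (-0.47, SE 0.0324) and COX4I1 (-0.54). COX4I1 stood at -1.24, -0.33 and -0.05 under siE1, siE2 and siE3, the last not called. In complex I, 22 of 37 fell and 1 rose (median -0.17, camera adjusted p = 3.9e-04, adjusted p = 0.35 with an estimated correlation), among them NDUFB5 (-0.37, SE 0.0461), NDUFAB1 (-0.33) and NDUFS1 (-0.30). With siE3 alone complex I did not pass (9 down, 2 up, median -0.04, camera adjusted p = 0.11), and 19 of the 41 genes of complexes II to V fell, against 31 with siE1 and 37 with siE2. In the TCA cycle 16 of 22 fell and 1 rose (median -0.23, camera adjusted p = 2.7e-05, adjusted p = 0.26 with an estimated correlation). OGDH was at -0.44, and pyruvate carboxylase (PC) rose by 0.43. Of 75 mitochondrial ribosome genes 44 fell and 2 rose (median -0.17, camera adjusted p = 1.6e-06, adjusted p = 0.35 with an estimated correlation), with MRPL35 at -0.62 and MRPL37 at -0.56. Adjusted over the list alone, 36, 22, 18 and 44 fell in these 4 lists. Of 17 genes described elsewhere as ERRα targets, ESRRA included, 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (median -0.14, camera adjusted p = 0.013, adjusted p = 0.24 with an estimated correlation), with MFN2 at -0.53, SE 0.0398. Without ESRRA, which the siRNAs lower by design, the other 16 had a median of -0.12 (camera adjusted p = 0.049). These 16 were not tested with an estimated correlation. The target list, ESRRA included, had medians of -0.13, -0.12 and -0.27 with siE1, siE2 and siE3 alone (camera adjusted p = 0.034, 0.13 and 0.0077; adjusted p = 0.33, 0.34 and 0.25 with an estimated correlation). Fatty acid oxidation (7 of 25 down, 4 up, camera adjusted p = 0.71) and glycolysis (11 of 23 down, 4 up, camera adjusted p = 0.22) did not pass, although ACSL1 (-0.67) and the hexokinase HK2 (-0.64) fell. Over 5618 genes free of the 3' UTR words found later, 5 of the 17 target genes were left and did not pass, at an unchanged median of -0.14 (camera adjusted p = 0.067).

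Lipid and lysosome genes rose. Of 25 cholesterol synthesis genes 18 rose and 1 fell (median 0.27, camera adjusted p = 3.1e-06, adjusted p = 0.17 with an estimated correlation). INSIG1 rose by 0.75 (SE 0.0712) and MSMO1 by 0.46. Of 16 fatty acid synthesis genes 10 rose and 1 fell (median 0.30, camera adjusted p = 4.3e-04, adjusted p = 0.14 with an estimated correlation), with ACLY above all, the elongase ELOVL5 (0.55) and the desaturases FADS1 (0.47) and FADS2 (0.47). Of 26 lysosome and autophagy genes 16 rose and 2 fell (median 0.30, camera adjusted p = 4.9e-05, adjusted p = 0.10 with an estimated correlation), including the protease CTSD (0.71), CTSZ (0.67), NPC1 (0.67) and LAMP2 (0.55). Adjusted over the list alone, 19, 10 and 16 rose in these 3 lists. Each of the 3 also passed with siE1, siE2 and siE3 alone. With an estimated correlation none of these calls held (adjusted p = 0.21, 0.29, 0.25 for cholesterol, 0.29, 0.18, 0.25 for fatty acids and 0.18, 0.18, 0.25 for the lysosome).

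Cell division and ribosome genes fell in the average, most of all with siE2. Of 41 DNA replication genes 30 fell and 3 rose (median -0.25, camera adjusted p = 2.1e-06, adjusted p = 0.44 with an estimated correlation), with RFC3 at -0.63, MCM10 at -0.55 and MCM3 at -0.50, while RFC5 rose (0.62). Of 40 mitosis genes 30 fell and 2 rose (median -0.21, camera adjusted p = 1.1e-06, adjusted p = 0.45 with an estimated correlation), with CDC20 at -0.51 and NUSAP1 at -0.41. The replication list did not pass with siE1 alone (16 down, 7 up, median -0.10, camera adjusted p = 0.25), nor the mitosis list with siE3 alone (12 down, 5 up, median -0.06, camera adjusted p = 0.14), and under siE2 37 genes of each fell. Of 55 cytosolic ribosomal protein genes 44 fell and 0 rose (median -0.15, camera adjusted p = 7.2e-08, adjusted p = 0.44 with an estimated correlation), such as RPL14 (-0.41). By siRNA, 22 of the 55 fell with siE1, 54 with siE2 and 5 with siE3, where the list did not pass (camera adjusted p = 0.56). Serine and folate genes (8 of 14 down, 2 up) fell in the average (median -0.18, camera adjusted p = 0.037, adjusted p = 0.45 with an estimated correlation), but passed with siE2 alone only (camera adjusted p = 0.0092, adjusted p = 0.34 with an estimated correlation). In the average 4 of 9 histone genes fell (median -0.46, camera adjusted p = 0.050, adjusted p = 0.44 with an estimated correlation), with a median of -0.82 under siE1 (camera adjusted p = 0.0088, adjusted p = 0.36 with an estimated correlation) and of -0.45 under siE3, which did not pass (0.11). Under siE2 2 histone genes rose and 1 fell (median 0.08, camera adjusted p = 0.99). Adjusted over the list alone, 31, 30, 46, 8 and 3 fell in these 5 lists. The last 2 did not pass without siC replicate 2 (camera adjusted p = 0.057 and 0.098), nor the histones without siE1 replicate 2 (0.064), without siE3 replicate 2 (0.065) or without a filter (0.069). Ribosomal protein, histone, keratin and ferritin genes have close copies in the genome, and how such reads were counted is not given in the sources used here.

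Adhesion, matrix and TGF-β genes rose in the average. Of 30 matrix proteases and inhibitors 20 rose and 2 fell (median 0.37, camera adjusted p = 1.6e-06, adjusted p = 0.10 with an estimated correlation), with the membrane collagenase MMP14 at 0.75, SE 0.0365, ADAM8 at 1.00, SE 0.0807 and the inhibitor TIMP3 at 1.02. Of 29 focal adhesion and integrin genes 18 rose and 4 fell (median 0.32, camera adjusted p = 1.0e-04, adjusted p = 0.37 with an estimated correlation), with the integrins ITGB4 (1.47, SE 0.0797), ITGB2 (1.35), ITGAV (0.97) and ITGA3 (0.75). Of 35 extracellular matrix genes 23 rose and 7 fell (median 0.45, camera adjusted p = 8.3e-05, adjusted p = 0.24 with an estimated correlation). COL5A1 (1.25) and COL6A1 (0.93) rose, while COL8A1 (-0.88) and CTGF (-0.69) fell. The matrix median was 0.25 without siC replicate 2. Of 19 TGF-β response genes 15 rose and 0 fell (median 0.39, camera adjusted p = 1.6e-06, adjusted p = 0.10 with an estimated correlation), with the receptors TGFBR1 (1.60, SE 0.0626) and TGFBR2 (0.49). TGFB2 stood at 0.66 under siE1, 1.92 under siE2 and -0.58 under siE3. Adjusted over the list alone, 20, 18, 24 and 15 rose in these 4 lists. Alone, siE1 did not pass for extracellular matrix (median 0.14, camera adjusted p = 0.073), and siE3 not for focal adhesion (median 0.14, 0.14) or TGF-β response (median 0.25, 0.0501). YAP and TAZ targets (12 of 20 up, 7 down) did not pass (camera adjusted p = 0.11), but did with siE2 alone (11 up, 3 down, median 0.48, camera adjusted p = 0.0068, adjusted p = 0.31 with an estimated correlation), against a median of -0.07 under siE3.

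Mesenchymal and epithelial markers were both higher in the average, by calls that hung on single siRNAs and libraries. Of 12 mesenchymal markers 6 rose and 1 fell (median 0.32, camera adjusted p = 0.029, adjusted p = 0.26 with an estimated correlation), with SNAI2 at 1.26, S100A4 at 1.45 and AXL at 0.45. Of 15 epithelial markers 7 rose and 2 fell (median 0.26, camera adjusted p = 0.050, adjusted p = 0.26 with an estimated correlation), with CLDN4 at 0.94, CLDN7 at 0.80 and JUP at 0.77. Of 6 basal markers 4 rose (median 0.41, camera adjusted p = 0.013, adjusted p = 0.24 with an estimated correlation), with MYLK at 0.58. Adjusted over the list alone, 7, 7 and 4 rose. Luminal (3 of 8 up, 3 down, camera adjusted p = 0.63) and endothelial markers (4 of 6 up, 1 down, camera adjusted p = 0.19) did not pass. Alone, siE2 passed for the 3 lists (adjusted p = 0.29, 0.29 and 0.23 with an estimated correlation) and siE1 and siE3 for none, and the epithelial median was -0.02 under siE3 (camera adjusted p = 0.60). Without siC replicate 2 the mesenchymal, epithelial and basal lists did not pass (camera adjusted p = 0.051, 0.077 and 0.051), and the mesenchymal median was 0.20. Without a filter the mesenchymal and basal lists did not pass (0.052 and 0.076), and the basal median was 0.06 there and 0.16 to 0.25 in some sets with a library left out. The epithelial list also did not pass with library size only (0.057), without siE1 replicate 2 (0.0507) or without siE3 replicate 2 (0.055), and its median was 0.49 without siC replicate 1.

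Interferon and cytokine genes rose in the average. Of 42 interferon response genes 22 rose and 3 fell (median 0.28, camera adjusted p = 0.0018, adjusted p = 0.32 with an estimated correlation), with IFIT1 (1.16, SE 0.0935), IRF1 (0.84) and B2M (0.29) up and EIF2AK2 (-0.37) down. Of 29 NF-kB and cytokine genes 15 rose and 2 fell (median 0.30, camera adjusted p = 0.0017, adjusted p = 0.53 with an estimated correlation), with ICAM1 (1.38), CSF1 (1.19) and IL11 (1.11) up and NFKB1 (-0.47) down. Adjusted over the list alone, 22 and 15 rose. Alone, siE3 did not pass for the interferon list (median 0.14, camera adjusted p = 0.11) and siE2 not for the NF-kB list (median 0.09, 0.20). The NF-kB median was 0.14 without siC replicate 1 and 0.52 without siC replicate 2, and the interferon median 0.17 without siC replicate 2. In all, 22 of 37 tested lists passed, 12 upward and 10 downward, and 0 held with an estimated correlation. With siE1, siE2 and siE3 alone 17, 20 and 12 passed, and again 0 held with an estimated correlation. The rotation test fry, which asks whether a list moves without comparing it with other genes, called 30.

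**Figure D3:**
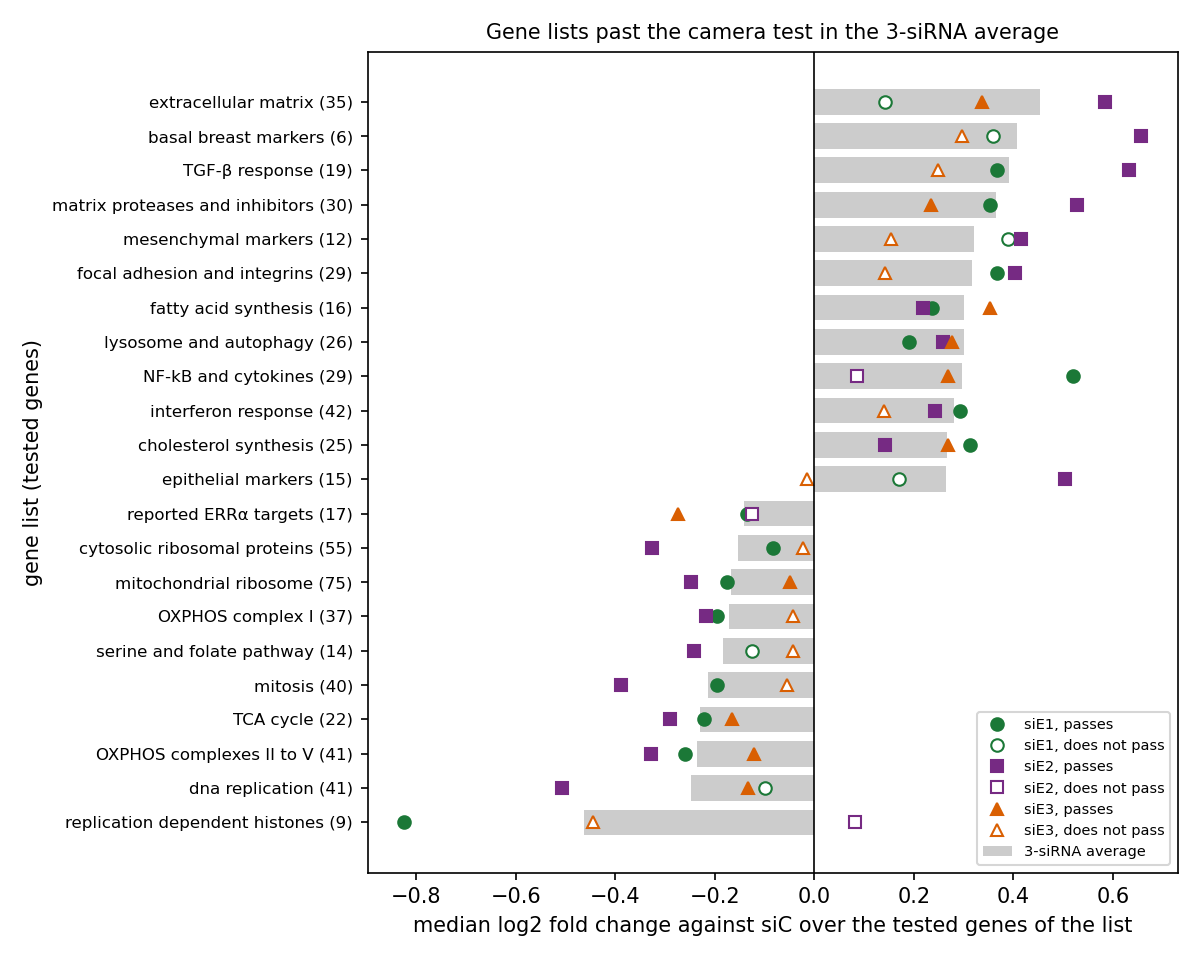
Median log2 fold change against siC (horizontal axis) over each list that passed in the average of siE1, siE2 and siE3 (vertical axis). Respiratory complexes II to V had a median of -0.24 in the average, and cytosolic ribosomal proteins -0.33 under siE2 and -0.02 under siE3.

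The siRNAs also differed from each other. Direct contrasts called 7654 genes between siE1 and siE2, 6529 between siE1 and siE3 and 6491 between siE2 and siE3, or 2556, 1827 and 1691 with at least 1.5-fold. Against siC, siE1 set apart IL1B (3.14, SE 0.295), APCDD1L (2.28), the tetraspanin CD82 (1.95), FSTL1 (-2.31, SE 0.0442), AIDA (-2.12) and TFB1M (-2.03), which modifies mitochondrial ribosomal RNA. With siE2 these were TP53INP1 (2.89), FILIP1L (2.70), the amino acid transporter SLC38A4 (2.66), TRIB2 (2.46), GPD1L (-2.50), CDC37L1 (-1.92), PPM1E (-1.84) and SCAMP5 (-1.73). With siE3 they were TMEM87B (2.41), PLSCR4 (2.37), CACNA2D1 (2.15), adrenomedullin (ADM, -2.04), thrombospondin-1 (THBS1, -1.79), IL6R (-1.64) and EIF4EBP2 (-1.60). Some of these differed between siRNAs in size only. Under siE1, siE2 and siE3, PLSCR4 lay at 2.11, 1.96 and 2.37, TMEM87B at 1.65, 2.09 and 2.41, and CACNA2D1 at 1.72, 1.81 and 2.15. CD82 lay at 1.95, 1.33 and 1.21, and IL1B at 3.14, 1.90 and 0.80. Others were near siC under the other siRNAs, such as FSTL1 (-2.31, -0.08 and 0.16) and TFB1M (-2.03, 0.02 and -0.03). THBS1 rose by 1.03 under siE2 and fell by 1.79 under siE3. Of 4446 genes called with both siE1 and siE2, 903 went opposite ways, as did 604 of 3642 for siE1 and siE3 and 505 of 4044 for siE2 and siE3.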

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

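The tests of the remaining ESRRA level, of library size and of the 3' UTR words as the whole cause were chosen only after the result was seen. Each result in this part stands out because 2 siRNAs against the same gene differed in edgeR's direct test, or in camera for lists. The contrasts called 7654 genes (siE1 against siE2), 6529 (siE1 against siE3) and 6491 (siE2 against siE3). Of 141 list members given as examples 132 differed between at least 2 siRNAs, as did 40 of 41 other named genes. These counts follow in part from the naming rule. Genes named for a single siRNA had to differ from both others, and list examples had the smallest p. Of all 13395 tested genes, 57.1% differed between siE1 and siE2, 48.7% between siE1 and siE3 and 48.5% between siE2 and siE3.

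For each named gene the widest called difference follows as a log2 value, the first siRNA minus the second. Between siE1 and siE2 it was 0.37 for ESRRA, 0.27 for RHOA, -1.92 for TP53INP1, -1.79 for TRIB2, -1.19 for TK2, -1.68 for KIF3B, 0.76 for C5orf62, 0.93 for SPNS2 and 2.26 for GPD1L. In the same pair TFB1M was at -2.06, FILIP1L at -2.24, SLC38A4 at -1.80, CDC37L1 at 2.17 and PPM1E at 1.76. Between siE1 and siE3 it was 1.11 for MMP1, 1.07 for TMEM64, 0.24 for TMEM65, -0.77 for TMEM87B, -0.43 for CACNA2D1, -0.54 for FAM155B, -1.39 for MGC12916, 0.61 for SNHG4, -1.37 for LIN52, -0.88 for HS3ST3B1 and -1 for RPIA. In that pair IL1B stood at 2.34, APCDD1L at 1.89, CD82 at 0.74, FSTL1 at -2.47, AIDA at -2.28, IL6R at 1.82 and EIF4EBP2 at 1.93. Between siE2 and siE3 it was -0.56 for TNFAIP1, -0.41 for PLSCR4, 0.50 for SLC22A18, -0.21 for ACLY, -0.43 for UHMK1, -1.05 for SCAMP5, 2.34 for ADM and 2.82 for THBS1.

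Between siE1 and siE2 the median log2 difference was 0.19 for glycolysis, -0.29 for matrix proteases and inhibitors, -0.44 for extracellular matrix, -0.24 for YAP and TAZ targets, 0.39 for DNA replication, 0.23 for mitosis, -0.86 for histones and 0.23 for cytosolic ribosomal proteins. Between siE2 and siE3 it was -0.14 for complex I, -0.18 for complexes II to V, -0.13 for the mitochondrial ribosome, -0.26 for serine and folate genes, 0.29 for focal adhesion, 0.47 for matrix proteases and inhibitors, and 0.32 for extracellular matrix. In that pair YAP and TAZ targets were at 0.50, DNA replication at -0.35, mitosis at -0.32, cytosolic ribosomal proteins at -0.30 and RNA interference machinery at -0.21. None of these list differences held with an estimated correlation.

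Off-target silencing through the siRNA seed, a short stretch that can pair with 3' UTRs, is a candidate explanation for the differences between siRNAs: genes with GACCAGA, a word also present in ESRRA, were lower with siE1 than with the others (t = -14.76, lowest of 100 permutations -4.71). The leading words of siE2 (TCTGCTA, t = -12.65) and siE3 (TCTCAGA, t = -12.08) also lay beyond the lowest of 100 permutations (-4.36 and -4.9). For both the rule set before this test was missed, since these words are absent from ESRRA. The absence alone does not count against a seed. The overlapping ATCTGCT, tied for the lowest t of siE2, and ATCTCAG (t = -7.94) are in ESRRA, as are 12.5% of all words tested. Joined into 8 bases, the 2 siE2 words give ATCTGCTA, and the 2 siE3 words ATCTCAGA. Relative to the other siRNAs, genes with ATCTGCTA had a median of -0.204 under siE2. It was -0.051 with a shorter word only and 0.025 with neither. Under siE3 the medians for ATCTCAGA were -0.095, -0.02 and 0.033. These words were picked on the same fold changes. For both siRNAs the question stays open, and the siRNA sequences are not given in the sources used here. Of 5618 genes with none of the words, 55.3% still differed between siE1 and siE2. The share was 64.1% of 3643 genes with a word of siE1 or siE2, and 57.1% of all tested genes. These shares cannot decide whether seeds are the whole cause. Other shifted words stayed in, such as ATGACCA for siE1 (t = -9.27) and CTGCTAT for siE2 (t = -9.37), as did any genes downstream of silenced ones. A different remaining level of ESRRA as the whole cause was argued against by a log2 difference of -0.065 (SE 0.113) between siE2 and siE3, below the bound of 0.25 with 1 SE added, a margin set after a first result, while 6491 genes differed; a part in the differences of siE1, where ESRRA was higher by 0.37 and 0.30, stays open. Group means of library size lay within a ratio of 1.062, against 1.16 for single libraries inside a group. Averaging narrows the first ratio, and library size is scaled in the fit, so this test cannot decide on library size.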

How the results depend on the processing

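No called result reversed, but lists that did not pass turned in places, such as the ATF4 list (camera direction up without siC replicate 2, adjusted p = 0.68) and the p53 list (median -0.04 without siC replicate 1). The counts of changed genes stayed within 1.5 times under the other scalings, filters, tests, blocks and left-out libraries. The shared genes ranged from 1519 (without siC replicate 2) to 2208 (no filter), with 1678 by DESeq2 and 1963 with the replicate number as a block. Replicate differences correlated at -0.40 (siC, siE1), -0.34 (siC, siE2), 0.26 (siC, siE3), 0.37 (siE1, siE2), -0.37 (siE1, siE3) and -0.34 (siE2, siE3). As given, the numbers do not pair the samples, and the signs would fit a common batch with siE1 and siE2 numbered in reverse, a hint from the data only. A block with these 2 crossed, added afterwards, gave 2725. Requiring at least 1.5-fold left 1974 (siE1), 2408 (siE2), 1335 (siE3), 1277 (average), 2556 (siE1 against siE2), 1827 (siE1 against siE3), 1691 (siE2 against siE3) and 338 shared genes, by construction. Genes without the 3' UTR words, a choice made after the data were seen, gave 2751, 3112, 2123, 2823, 3086, 2621, 2577 and 840 in that order, with 5618 genes tested. With ESRRA left out of the lists, a choice made afterwards, 22 passed. Against 22 lists, 0 passed with an estimated correlation and 12 with siE3 alone. A higher correlation cannot be the reason in every list. The ERRα target list had an estimate of 0.0106, near the preset 0.01, and its camera adjusted p went from 0.013 to 0.24. For the lysosome list the estimate was -0.021, and the camera adjusted p went from 4.9e-05 to 0.10. Other lists had estimates above the preset, such as 0.60 for mitosis. What else cost the calls was not tested. Of other values for named genes 3154 kept their status, whether called or not, 31 lost a call and 9 gained one, and for lists 454, 14 and 8. A lone library left in a group was assumed to vary like the others. The pseudocount and low-value choices for normalized values were not run because the table holds counts. Small changes are limited by 2 libraries per group, with 38% to 54% of simulated changes of 0.25 recovered.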

Other observations

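The tests over genes without the 3' UTR words, with their lists, were chosen only after the words had been seen. Genes of the RNA interference machinery moved in both directions (4 of 16 up, 4 down, camera adjusted p = 0.86): EIF2C4 rose by 1.17 (SE 0.0687) and DICER1 by 0.64, while XPO5 (-0.66) and GEMIN4 (-0.42) fell. Of 22 NRF2 targets 9 rose and 3 fell (camera adjusted p = 0.054), with siE3 passing alone (7 up, 1 down, camera adjusted p = 0.019, adjusted p = 0.72 with an estimated correlation) and siE1 (11 up, 5 down, 0.073) and siE2 (0.83) not, and with TXNRD1 at 0.61, FTH1 at 0.55 and HMOX1 at 1.63, 0.20 and 0.58 under siE1, siE2 and siE3. The NRF2 list passed with library size only (camera adjusted p = 0.043), without a filter (0.034) and without siC replicate 2 (0.030), siE1 replicate 2 (0.031), siE2 replicate 2 (0.031) or siE3 replicate 1 (0.038). Its median was 0.10 over all genes and 0.36 over the genes without the 3' UTR words (0.0058). With an estimated correlation the NRF2 list had a camera adjusted p of 0.64 in the average, and the alternatives were not run that way. Of 22 p53 targets 8 rose and 6 fell (camera adjusted p = 0.53), with PHLDA3 at 1.23 and FBXW7 at -0.47. Hypoxia genes (9 of 27 up, 6 down, camera adjusted p = 0.30), unfolded protein response genes (8 of 20 up, 5 down, 0.17) and immediate early genes (4 of 19 up, 3 down, 0.62) did not pass in the average. Hypoxia genes passed with siE1 alone (12 up, 3 down, camera adjusted p = 0.024, adjusted p = 0.33 with an estimated correlation). Over the genes without the 3' UTR words the unfolded protein response passed as well (median 0.18, camera adjusted p = 0.0014). That subset was not run with an estimated correlation, which over all genes gave this list a camera adjusted p of 0.48. NDRG1 (0.70), CALR (0.40) and KLF6 (0.56) rose. ATF4 response genes (5 of 26 up, 8 down) had a median of -0.10 and a mean of 0.05 (camera direction down, adjusted p = 0.74), with DDIT4 at 1.34 and SARS at -0.34.

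The genes that all 3 siRNAs moved alike could come from loss of ERRα, from the shared control libraries or from off-target silencing by the control siRNA, which would lower its targets under siC alone. For the shared control libraries, simulated unchanged groups gave at most 1 shared call, which speaks only to the spread between replicates, and a difference common to both siC libraries stays open. With siC replicate 1 or siC replicate 2 left out, 1727 and 1519 genes were shared. For off-target silencing by siC, genes with TACATTT in the 3' UTR were higher in the 3-siRNA average (t = 14.22, highest of 100 permutations 5.12), and neither this word nor ACATTTA is in ESRRA. Off-target silencing by siC is thus a candidate explanation for part of the rises, including TMEM64 and ACLY, while a 3' UTR element that responds to loss of ERRα was not tested.

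The lower oxidative phosphorylation genes may follow from loss of ERRα, from a trend with transcript length and GC content, or from 3' UTRs that lack the control word. After a fit on length and GC content the median of 78 genes was -0.20, against -0.216 before and 95% limits of -0.125 to 0.029 in random lists. Among the 64 genes without the word it was -0.219, with matched lists at -0.114 to 0.051. The random and matched lists treat genes as independent. Estimated correlations were 0.126 in complex I and 0.269 in complexes II to V, so these limits are too narrow to decide. The fit took 3.2% of the variance of the fold changes and left the median nearly unchanged. All 8448 searched genes without the word had a median of -0.033. By their size only, with no usable limit beside them, these medians argue against both technical explanations as the whole cause. Loss of ERRα stays open. The size of the fall did not follow ESRRA. Complexes II to V were lower with siE2 than with siE3 by a median of -0.18 (camera adjusted p = 2.6e-06, adjusted p = 0.53 with an estimated correlation). Complex I was lower by -0.14, while ESRRA differed by -0.065. Effects of single siRNAs on these genes were not tested. The list test did not hold with an estimated correlation, and a shared response to transfection that differs between siC and the others was not tested.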
